A study of Danio rerio with 10 samples.

How the data were processed

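RNA sequencing was done on total RNA of whole zebrafish embryos at 28 hpf, with paired-end reads on a HiSeq instrument per the labels' protocols, in 4 wild-type and 6 uts2r3 homozygous mutant libraries. The authors deposited 1 table of raw counts per gene, with a gene length in bases and 1 column of whole-number counts for each of the 10 libraries. Per the file headers, the counts came from alignments named after the Subread package. The submitters' processing notes name cutadapt, DESeq2 and the genome builds GRCz11 and danRer11, with no role or version. The gene annotation, the read counter, its strand setting and its treatment of reads shared between genes are not given in the sources used here, so overlapping, antisense and near-identical genes may share or lose counts. The table holds no coordinates, no gene symbols and no rows of unassigned reads.

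Columns were matched to samples by the library name in the labels. The wild-type columns carry the prefix new before that library name, which the labels do not explain. Groups and replicate numbers were taken from the sample titles. No column was left over. All 36351 identifiers begin with LL, and 0 of them matched the gene name table or the RefSeq gene table supplied for zebrafish. The planned report of uts2r3, the planned tests of 32 gene lists and the planned test of calls per chromosome were not run for this reason, and no gene was named from its identifier or its place in the table. The comparison, the main test, most alternatives and the rule for the genes to name were fixed before the data were examined. Groupings of genes by abundance, length and near silence were chosen afterwards.

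Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype (24608 of 36351 genes, which held over 99.9% of the counts of each library), library sizes were scaled by TMM, and genotype was tested with glmQLFit and glmQLFTest with robust estimation. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are mutant against wild type, and the standard error of a log2 change is its size divided by the square root of the quasi-likelihood F. Normalised CPM are counts divided by the TMM-scaled library size. The median log2 change over all genes tested was 0.004. The test was tried on simulated counts with the real means, dispersions and library sizes and 200 changed genes. Principal components used log2 CPM with a prior count of 2, over 20047 genes with a CPM of at least 1 in at least 4 libraries. Comparisons of a value per library used exact two-sided permutation tests over the 210 arrangements of the libraries into 4 and 6, whose smallest p is 0.00952.

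The rule for genes to name took the 10 largest changes in each direction (adjusted p under 0.05, a mean of at least 1 CPM and no overlap of the groups) and the 5 smallest p in each direction, besides members of the gene lists. Since identifiers without names say little, only the leading gene of each of these parts is given by identifier, 2 in each direction, and the others are summarised.

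Alternatives were DESeq2 1.42.0 with its own size factors and filtering in place of edgeR, RLE size factors, total library size only, no low-count filter (any gene with at least 1 count), a CPM of at least 1 in at least 4 libraries, limma-voom (limma 3.58.1), a surrogate variable (sva 3.50.0), replicates 1 to 4 with and without the replicate number as a block, a 2-fold minimum and each library left out in turn. Thinning every library to the smallest total (31247787 counts) by binomial sampling, and an offset for each library's trend with gene length, were added after seeing the data. Replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.20 to 41.7 over pairs, so none was treated as a duplicate. Depth sets the floor: 3 counts correspond to 0.0134 CPM over the 6 mutant libraries together, and floors and binomial intervals cover counting error only.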

Results

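Gene expression was measured by RNA sequencing of total RNA from whole zebrafish (Danio rerio) embryos at 28 hours post-fertilization (hpf), in wild-type embryos and in embryos homozygous for a mutation in uts2r3, which encodes a receptor for urotensin-related peptides. The series concerns the mechanical state of the body before the spine curves in a fish model of idiopathic scoliosis, and its design implies the comparison of the mutant with the wild-type transcriptome at this age. The labels gave 4 wild-type and 6 mutant libraries, whereas the extraction note gave 5 controls and 5 mutants for RNA sequencing; the grouping followed the labels of the individual samples. The labels did not say how many embryos went into a library or whether the libraries came from separate clutches, so the p-values below measure the spread between these libraries, which may be technical. Total counts over genes were 62001742 to 73442336 per wild-type library and 31247787 to 42423874 per mutant library, a difference of 1.77 times between the group means that separated all 6 mutant libraries from all wild-type libraries.

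The deposited table named its 36351 genes by identifiers that begin with LL and did not pair them with gene symbols, and 0 of these identifiers matched the gene name tables used here. The level of uts2r3 itself, muscle, notochord, matrix and other gene lists, and chromosome positions were therefore not analysed here, and genes are described by their level, length and change. Because uts2r3 was not identified among the rows, the genotype labels have no check from the targeted gene.

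The mutant libraries differed from the wild-type libraries at many genes. Separate preparation or sequencing of the groups cannot be told apart from genotype, because the columns of each genotype carry their own series of names. Of 24608 genes tested, 1570 were higher and 1305 were lower in the mutants at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6 mutant against 4 wild-type libraries), which was 11.7% of the genes tested. The genes that rose had a median change of 1.44-fold, and 845 of them rose by less than 1.5-fold. The genes that fell had a median change of 1.67-fold, and 541 of them fell by less than 1.5-fold. In 1215 of the genes that rose, every mutant library lay above every wild-type library, and in 1004 of the genes that fell, every mutant library lay below. Over all genes tested the groups did not overlap at 11.8% of genes, where chance gives 0.952%. The number of genes that rose was 983 without wild-type replicate 1, 1047 without wild-type replicate 2 and 1011 without wild-type replicate 3. The common biological coefficient of variation between libraries was 15.02%. The 6-against-4 comparison was also simulated over 24608 genes. The test recovered 50.7% of genes changed 1.5-fold, 70.15% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls among 151. No change under 1.5-fold was simulated. The simulation also held far fewer changed genes than were called in the data, and the adjustment is stricter when fewer genes change. Changes under 1.5-fold may have been missed in the real comparison, but these rates do not measure how many.

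**Figure D1:**
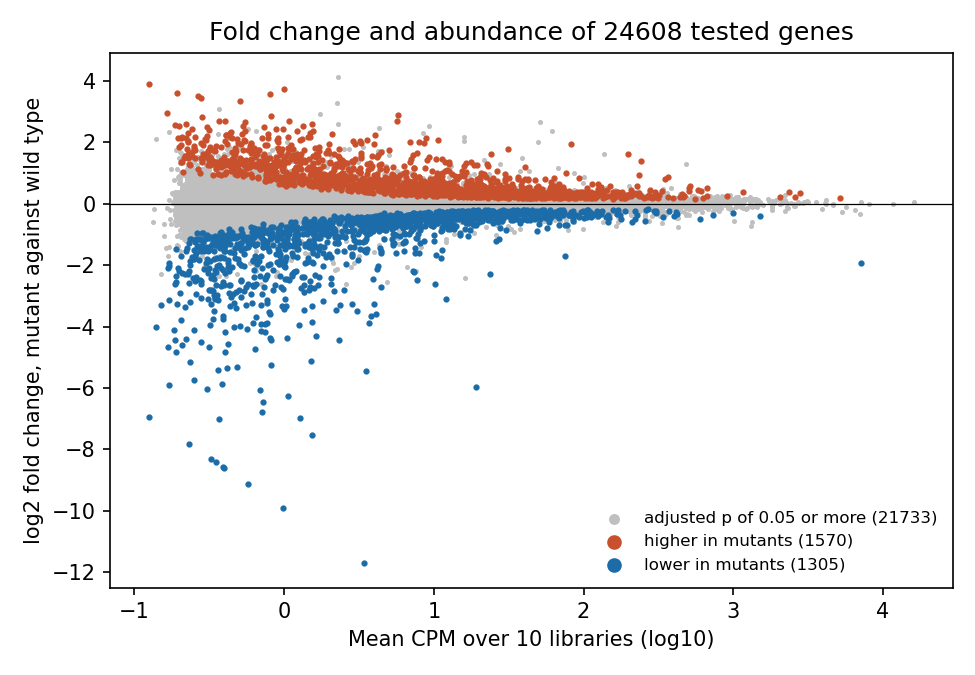
Fold change of each of 24608 tested genes (y axis, log2, mutant against wild type) against its mean CPM over the 10 libraries (x axis, log10 scale), with 1570 genes higher in mutants in orange, 1305 lower in mutants in blue and 21733 not called in grey. Genes far below the zero line outnumber those far above it; the most extreme negative values belong to genes with few or no mutant counts and depend on the prior count of the fit.

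The direction of change depended on its size. Among called genes with at least a 2-fold change (a log2 change of 1), 398 were higher and 497 were lower in the mutants. Among those with at least a 4-fold change (a log2 change of 2), 74 were higher and 219 were lower. The counts depended on the processing: 28 were higher and 76 lower with a CPM of at least 1 in at least 4 libraries. DESeq2 gave 117 higher and 373 lower. With every library thinned to the same total, the numbers at 4-fold were 62 higher and 188 lower, so the excess of large decreases was also present at equal depth.

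The direction also depended on abundance. Among the 1000 most abundant genes tested, 73 rose and 26 fell. Among the 10000 most abundant, 667 rose and 340 fell, so that 66.2% of the calls were increases. Among the remaining 14608 genes, 903 rose and 965 fell, and 48.3% of the calls were increases. The split between these abundance classes had a Fisher's exact p of 2.98e-20 (two-sided, across genes, which are not independent replicates). Abundance was the mean over all 10 libraries, so a change in the mutants also moved a gene's rank. Class and direction were therefore partly linked by construction. With DESeq2-style size factors (RLE), 62.0% of the calls among the 10000 most abundant genes and 46.3% of the others were increases. Among the 1000 most abundant genes, 47 rose and 30 fell with no low-count filter, and 123 rose and 80 fell with a surrogate variable. The overall balance changed with the filter: with no low-count filter, 33952 genes were tested, of which 1208 were higher and 1454 lower, so that 45.4% of the calls were increases. The shift was not limited to the added genes. Among the genes of the main test, 56.8% of the calls in the 10000 most abundant and 43.5% of the other calls were then increases.

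Of the 20 most abundant genes, 1 rose, 1 fell and 18 did not pass the test. The gene that fell was the fourth most abundant over all libraries, 1683 bases long by the deposited table. It fell from 12816 ± 2200 normalised CPM (SD, n = 4) in wild type to 3372 ± 323 (SD, n = 6) in the mutants, a 3.80-fold lower level, with a log2 change of -1.93 (SE 0.10) and an adjusted p of 2.29e-07 by edgeR. Its wild-type libraries lay between 10831 and 15828 CPM and its mutant libraries between 2942 and 3801 CPM. This gene took 1.28% of all counts in wild-type libraries and 0.337% in mutant libraries. It was among the 5 genes with the smallest p that fell. The gene that rose was the tenth most abundant and went from 4763 ± 169 CPM (SD, n = 4) to 5381 ± 171 CPM (SD, n = 6), with an adjusted p of 0.0453 by edgeR. That call was lost in 16 of 21 alternative analyses, where its log2 change lay between 0.15 and 0.19.

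The 20 most abundant genes together took 12.5% ± 0.385 of the counts in wild type (SD, n = 4) and 11.3% ± 0.196 in the mutants (SD, n = 6). This share was lower in 6 of 6 mutant libraries than in any wild-type library (exact two-sided permutation test over 210 arrangements, p = 0.00952, the smallest the design allows; p = 0.0222 after Benjamini-Hochberg adjustment over 7 library measures). Without the fourth most abundant gene, the share of the other 19 was 11.2% ± 0.269 in wild type and 11.01% ± 0.193 in the mutants (SD, n = 4 and n = 6), and the exact permutation p was 0.171 (0.24 adjusted).

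The largest and the most certain changes are given by identifier for 4 genes, 2 in each direction. LL0000024918, 8428 bases long, had the smallest p of all genes. It fell from 46.7 ± 10.6 CPM in wild type (SD, n = 4; 2457 to 3705 counts per library) to 0.760 ± 0.269 CPM in the mutants (SD, n = 6; 19 to 41 counts per library). That was a 61.4-fold lower mean level, with a log2 change of -5.96 (SE 0.20) and an edgeR adjusted p of 5.74e-08. LL0000017667, 2454 bases long, had the largest decrease. It was present in all 4 wild-type libraries, with 293 to 856 counts and 8.57 ± 3.56 CPM (SD, n = 4), and had 0 counts in all 6 mutant libraries. Against a floor of 3 counts over the mutant group (0.0134 CPM), it was at least 641-fold lower in the mutants (edgeR adjusted p = 4.99e-04). The floor covers counting error only.

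LL0000034473, 957 bases long, had the smallest p among the genes that rose. It went from 0.381 ± 0.070 CPM (SD, n = 4; 18 to 29 counts per library) to 2.31 ± 0.266 CPM (SD, n = 6; 64 to 112 counts), a log2 change of 2.59 (SE 0.18) with an edgeR adjusted p of 2.07e-06. LL0000012875, 5991 bases long, had the largest increase among genes averaging at least 1 CPM whose groups did not overlap. It went from 0.242 ± 0.361 CPM (SD, n = 4) to 1.64 ± 0.248 CPM (SD, n = 6), a log2 change of 2.71 (SE 0.64) with an edgeR adjusted p of 0.0214. Its wild-type mean rested on replicate 4, which held 56 counts where the other 3 libraries held 2 to 6. Without wild-type replicate 4 its log2 change was 4.66 (adjusted p = 4.50e-06). Without wild-type replicate 1 it was 2.45 (adjusted p = 0.0568), without mutant replicates 5 and 6 it was 2.62 (adjusted p = 0.0667), and with a replicate block added to the latter it was 3.22 (adjusted p = 0.0825).

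**Figure D2:**
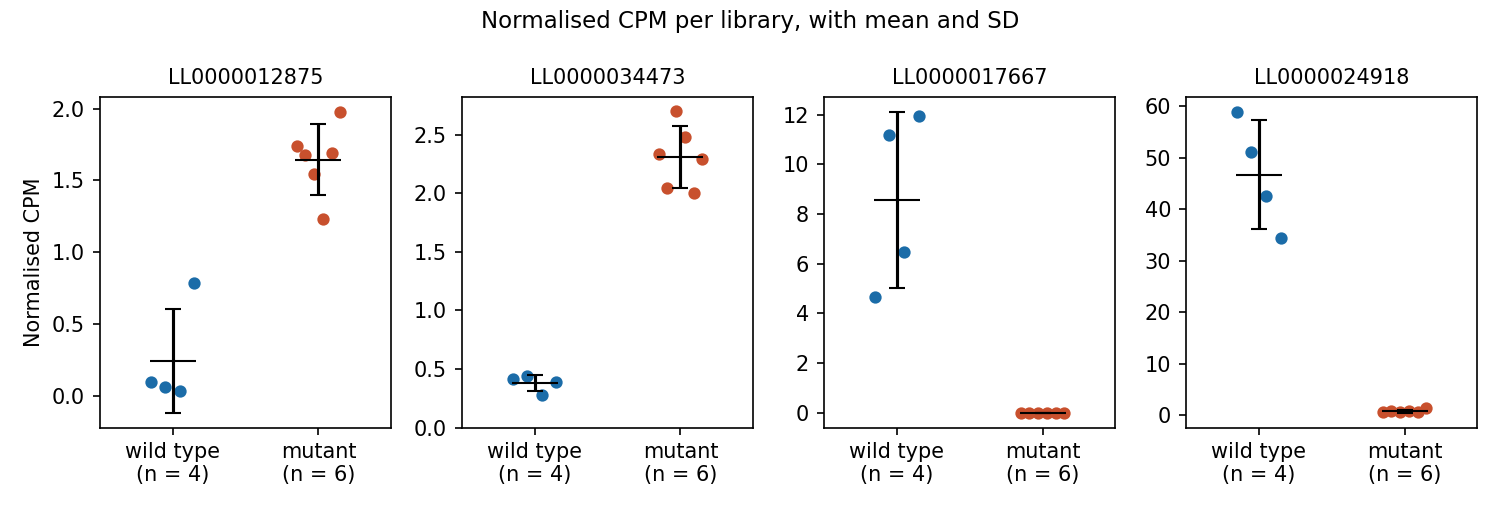
Normalised CPM (y axis, linear, a separate scale per gene) of the 4 genes given by identifier in 4 wild-type (blue) and 6 mutant (orange) libraries; points are libraries, the wide bar is the mean and the whiskers are 1 SD. In each gene the groups do not overlap, and LL0000017667 is at 0 in all 6 mutant libraries.

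The 10 largest increases and the 10 largest decreases were taken among called genes averaging at least 1 CPM whose groups did not overlap. The 10 increases had log2 changes between 2.18 and 2.71, at mean levels of 1.08 to 5.67 CPM. The 10 decreases had log2 changes of -3.97 and beyond, at mean levels of 1.04 to 19.1 CPM. The 5 genes with the smallest p among those that rose had log2 changes between 0.99 and 2.59. The 5 with the smallest p among those that fell had log2 changes between -5.96 and -1.52.

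Some genes were present in one genotype and near silent in the other. With at least 1 CPM in every library of one group and at most 3 counts summed over the other, a definition chosen after the table was seen, 4 genes were wild-type-only and 0 were mutant-only. Of the 4, 3 had no count in any mutant library, and their wild-type means were 107 to 641 times the floor of 3 counts over the mutant group. The upper 95% exact binomial limits of their depth-corrected mutant to wild-type ratios were 0.00190 to 0.0116 (counting error only). Without mutant replicate 2, 8 genes met the definition in place of 4, though leaving out a library can only keep or raise this number. The fourth had 466 counts over the wild-type libraries and 3 over the mutant libraries, a depth-corrected ratio of 0.00762 (95% exact binomial interval 0.00156 to 0.0224, counting error only).

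The share of called genes fell with gene length. It was 13.7% in the shortest of 5 equal classes of the genes tested by length (62 to 1622 bases; 384 rose and 291 fell) and 8.78% in the longest class (5817 to 102967 bases; 208 rose and 224 fell). The median log2 change was 0.03 in the shortest class and -0.03 in the longest. Within libraries, the longest minus the shortest class differed by 0.03 ± 0.15 (log2, SD, n = 4) in wild type and by -0.02 ± 0.11 (SD, n = 6) in the mutants, less than the spread between libraries (exact two-sided permutation p = 0.61).

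More genes were detected in wild-type libraries (30702 to 31873 genes with at least 1 count) than in mutant libraries (29626 to 30169; exact two-sided permutation p = 0.00952, 0.0222 adjusted, n = 4 and n = 6). With every library thinned to the smallest total, the numbers were 30095 ± 526 (SD, n = 4) and 29643 ± 340 (SD, n = 6), and the difference was within the spread between libraries (exact permutation p = 0.143, 0.24 adjusted).

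The libraries separated by genotype, and so also by series of column names, along the first principal component. This component held 43.0% of the variance of log2 CPM over 20047 genes. Wild-type libraries scored between -36.5 and -33.9 and mutant libraries between 16.1 and 30.5. The second component held 14.01% of the variance and separated mutant replicates 5 and 6, at -27.1 and -25.0, from mutant replicates 1 to 4, at 6.90 to 25.6. Wild-type replicate 4 lay on the same side as mutant replicates 5 and 6, at -16.7, where the other wild-type libraries scored 1.57 to 7.15, and it had the lowest score on the third component, at -28.8. Its longest minus shortest length class was -0.20 (log2), against 0.07 to 0.14 in the other wild-type libraries. This value was -0.18, -0.08 and -0.10 in mutant replicates 5, 6 and 3, and 0.05 to 0.11 in mutant replicates 1, 2 and 4. Correlations of log2 CPM across genes were 0.983 to 0.990 between wild-type libraries, 0.978 to 0.990 between mutant libraries and 0.964 to 0.976 between genotypes. With mutant replicates 5 and 6 left out and the wild-type libraries kept, 1585 genes were higher and 1571 lower in the mutants, and 77.6% of the genes called with all libraries were called again in the same direction.

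**Figure D3:**
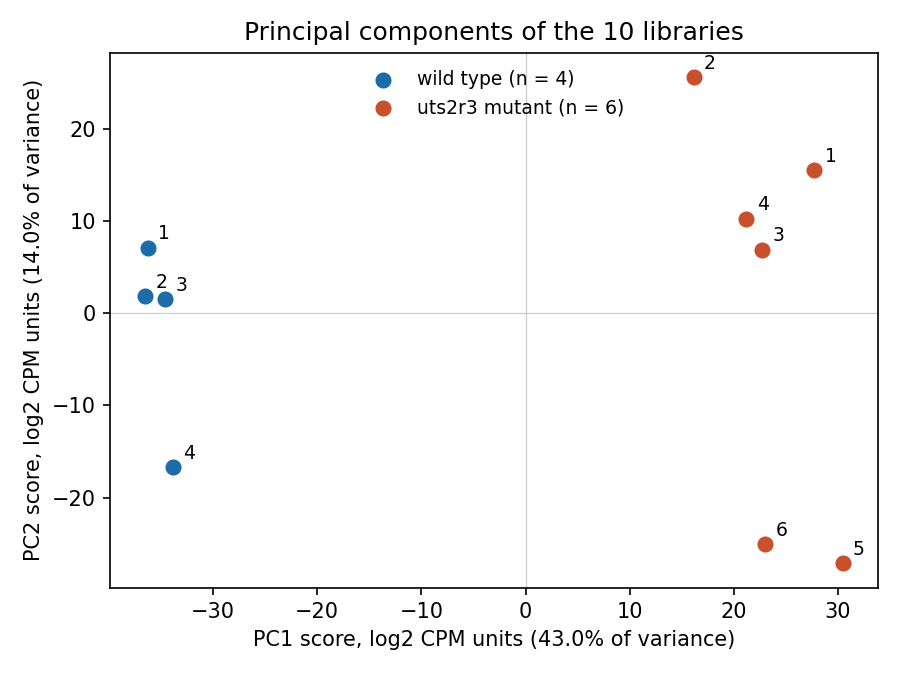
Scores of the 10 libraries on the first (x axis, 43.0% of variance) and second (y axis, 14.01% of variance) principal components of log2 CPM; numbers are the replicate numbers, blue is wild type and orange is mutant. The genotypes lie on opposite sides of the first component, and mutant replicates 5 and 6 lie below the other mutant libraries on the second, as wild-type replicate 4 does below the other wild-type libraries.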

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

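The tests behind these values were applied to 27 sets of library values, of which chance alone is expected to flag about 1 in 20, or 1.35; 2 were flagged. LL0000012875 was at 0.782 CPM in wild-type replicate 4, far from the other wild-type libraries at 0.031 to 0.095 CPM. LL0000024918 was at 1.29 CPM in mutant replicate 6, apart from the other mutant libraries at 0.580 to 0.759 CPM, and still far below the 34.3 CPM of its lowest wild-type library.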

How the results depend on the processing

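The counts of genes higher and lower in the mutants stayed within 1.5 times of 1570 and 1305 under 11 alternatives: DESeq2 with its own filter (29333 genes tested) gave 2031 and 1904, the surrogate variable 2096 and 1947, the CPM filter 1209 and 1024, and no low-count filter 1208 and 1454, where the lower genes outnumbered the higher ones. On simulated counts DESeq2 made 38 false calls among 194, limma-voom 10 among 156 and edgeR 6 among 151. The counts were drawn in a single simulation with dispersions estimated by edgeR. They therefore do not show whether the added DESeq2 calls in the real data are false. Requiring a 2-fold change gave 398 and 497 by its construction. Leaving out each library in turn gave 983 to 1400 higher and 916 to 1274 lower genes. Without wild-type replicate 1 (983) or wild-type replicate 3 (1011) the count of higher genes fell by over 1.5 times. Without wild-type replicate 2 (1047) it stayed barely within that bound. Between 61.8% and 82.5% of the called genes were called again in the same direction with a library left out, and 0 were called in the opposite direction in any of these fits. At least 4-fold decreases outnumbered increases under every alternative. Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated at 0.16, 0.09, -0.05 and -0.07. Wild-type replicates 1 and 2 each correlated best with the mutant library of their own number, and wild-type replicates 3 and 4 with another. With the replicate block over replicates 1 to 4, 1328 genes were higher and 1352 lower. Of 126 recalculated fold changes of the 4 identified genes and the 2 called genes among the 20 most abundant, none changed sign and 19 lost significance, 16 of them for the tenth most abundant gene and 3 for LL0000012875, whose log2 change ran from 2.35 to 4.66, the highest without wild-type replicate 4. The 4 near-silent genes became 8 without mutant replicate 2. By the definition, leaving out a library could only keep or raise this number, so it does not check the 4 genes. Alternatives planned for uts2r3, the gene lists and the chromosomes were not run. Depth limits the genes near the floor.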

Other observations

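Calls were not spread evenly along the deposited identifiers. The hypothesis that called genes gather among neighbouring identifiers was tested by shuffling: 313 pairs of adjacent tested identifiers were called in the same direction, against a median of 197 and a central 95% range of 172 to 223 in a permutation test of 10000 shuffles within blocks of 200 identifiers (p = 1e-04, the smallest these shuffles can give). At distances of 2, 3, 5, 10, 50 and 100 identifiers the numbers were 215, 221, 228, 203, 193 and 184, and of these only the 228 at a distance of 5 lay above the upper limit of its own shuffles (222). The largest number of called genes in 30 adjacent tested identifiers was 20, where 3.50 would be the average, and 3 overlapping stretches, shifted by 1 and 2 identifiers, held that number. In the first of them, 9 of the 20 genes were higher and 11 were lower in the mutants. This first stretch began at LL0000017667, the gene with 0 counts in all mutant libraries, which the other stretches did not hold. Its 30 genes had a median level of 0.82 CPM, against 8.25 CPM over all genes tested. Shuffles that kept the number of calls in each of 10 abundance classes gave at most 16 in any stretch. In the data, 46 stretches of 30 identifiers held more than that. These stretches can overlap, so their number does not count separate places. The tests of the densest stretch and the shuffles at distances over 1 were chosen after the result was seen. Whether neighbouring identifiers are neighbours in the genome was not tested, so a chromosome region, a gene family or overlapping gene models remain open for this pattern.

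The 2875 calls between genotypes were weighed against technical explanations. Of 100 splits of the 10 libraries into 4 and 6, only the real one called as many genes, and the highest other split called 220. That other split set mutant replicates 1 to 4 against the rest. A random grouping would thus seldom call as many genes, at the 1 in 100 that these splits can resolve. All other splits mixed the genotypes, so the genotype difference widened the spread within their groups and lowered their calls. After thinning to equal depth, 81.0% of the genes were called again in the same direction, and after removing each library's trend with gene length, 92.8% were, so neither the greater depth of the wild-type libraries nor a length trend could be the whole cause. Separate preparation or sequencing of the genotypes cannot be told apart from genotype, because 0 series of column names held both genotypes and total counts differed completely between them; strain background and developmental timing stay open and untested as well.

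On average, mutant replicates 5 and 6 stood apart from mutant replicates 1 to 4: distances between the sets were 1.297 times those within them. The sets were those that the second principal component of the same data separated, so the ratio is not separate evidence. Mutant replicate 6 correlated slightly better with mutant replicate 4 (0.987) than with mutant replicate 5 (0.985). The ratio was 1.28 with the mutant libraries thinned to equal depth and 1.28 with the length trend removed, above the bound of 1.1 set before these values were seen, so neither accounts for the whole separation. Wild-type replicate 4 lay on the same side of the second principal component (-16.7), and whether it shares their difference was not tested. The labels give these libraries no batch, clutch or other difference, so no biological explanation was tested.

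The 4 genes present in wild type and near silent in the mutants were set against depth in a test chosen after the result was seen. At equal depth, 15 sets of 4 wild-type and 4 mutant libraries gave 6 to 11 wild-type-only genes and 0 mutant-only genes, and 20 thinnings of all libraries gave 4 to 6 and 0, so the greater depth of the wild-type libraries could not be the whole cause. The 4 genes are among the 2875 calls, and chance was not tested on them separately, since they were chosen for their difference. An allele that differs from the reference sequence in the mutant stock, a linked chromosome region and an effect of the mutation stay open, and were not tested.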
